A study of Mus musculus with 28 samples.

How the data were processed

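Single-cell RNA was measured in 28 libraries of KPC mice, 16 from pancreatic tumors and 12 from uninvolved pancreas, with the 10x Chromium 5' v2 kit per the labels. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17, aligned to mm10 and counted with Cell Ranger 3.1.0, and analysed with Seurat 2.3.4; the aligner's settings are not given in the sources used here. The deposited matrices hold UMI counts per gene and barcode as whole numbers, 1 matrix per library, which were checked to be unscaled; they are the output the authors deposited, before any clustering. Nothing beyond these counts was taken from the authors. Gene positions came from the GENCODE vM21 annotation (GRCm38), matched by Ensembl identifier. The libraries hold 261999 to 64358519 UMIs, so the precision of a class can differ between libraries.

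Groups were taken from the labels' tissue. The titles fall into 3 sets (LDER, Un and other), each with both tissues. The set was a term in the main gene models and a stratum in the permutation tests of shares, since it may mark a batch. Partners in the chromosome match were permuted over all sets. Numbers shared by a tumor and a normal title were not taken as pairs: of 10 such couples 4 differed in sex genes, and profiles of couples correlated at -0.110 to 0.0870 in macrophages (5 couples), -0.0779 to 0.187 in T cells (3) and -0.0232 to 0.0204 in fibroblast-like cells (4). The tumor correlated best with the normal of its own number in 2 of the 5 and 1 of the 3, the latter LDER 4 at 0.187, so pairs among them are not excluded. 1 further couple, tumor replicate 6 and normal replicate 2, both male, shares a name in the other set; it entered the replicate block and not this check.

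Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs. Likely doublets were scored per library by the Scrublet method with 0.8% expected per 1000 barcodes, which left 48863 of 50344 cells. Counts were scaled and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1 (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0). Clusters were named from marker lists of 16 classes fixed before the data were examined: at least 3 markers in 10% of cells and a mean score of 2 (log2) above the other clusters. Classes are called "-like" since no sort or stain names the cells, and the class of T or NK cells is called T cells. Details of the naming were set after the clusters were seen: the median over clusters as reference, a rename where another class holds more of the leading genes, no class for a cluster with at least 95% of its cells from 1 library or with intestinal genes. Stromal clusters were clustered again to part fibroblasts from pericytes and mesothelial cells.

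Shares of each class were compared over libraries with at least 100 kept cells by a two-sided permutation test with 100000 resamples of the labels within title set, with Benjamini-Hochberg adjustment over classes. For gene tests UMI counts were summed per library and class, and compared by edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The planned minimum was 20 cells per library. For fibroblast-like cells this left 1 normal library, so 5 cells were used, chosen after the cell numbers were seen; for ductal-like cells a minimum of 10 cells, listed before the data were examined as another setting, was used, also after the cell numbers were seen. Endothelial-like cells could not be tested. Neutrophils, B cells and dendritic cells were added after the data were seen. The genes named in the text are, by a rule set before the data were examined, the 10 per direction with the smallest p in fibroblast-like cells and the 5 per direction in other classes, without mitochondrial, ribosomal, predicted, acinar enzyme and haemoglobin genes, and members of 28 gene lists fixed at the same time, of which those for endothelial cells had no test. A few genes that the rule or the lists name are not given singly here. Lists were tested with fry and camera (limma 3.58.1), camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a class. Genes named in the text beyond these as leading genes of a cluster, and Hmga2, Cdkn2a, Epcam and Vim in single clusters, were chosen after their values were seen. Genes with near-identical copies, such as the haemoglobin, trypsin and amylase genes, may share reads between copies, and 5' counts were taken as deposited.

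The gene test was tried on simulated sums per library with known changes of 200 genes, drawn with the means and spread of the real ones. Filtering, clustering and naming of cells were not simulated. At 4-fold it recovered 77.4% for fibroblast-like, 40.8% for ductal-like, 98.6% for macrophage-like and 98.5% for T cells; at 2-fold 15.5%, 0%, 50.0% and 53.4%. Of the calls 3.15%, 1.45%, 4.09% and 8.84% were wrong.

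For the planned chromosome match, the median over genes of each autosome of the log2 ratio to the other tumors was taken per class after thinning to a common number of UMIs, and fibroblast-like and ductal-like profiles of the same tumor were correlated, with one-sided permutation of the partners. The planned profile against normal libraries could not be made, with 1 normal library of at least 20 fibroblast-like cells. Chosen after seeing the data were the SD comparison with an exact sign-flip test, the correlation between the 2 equal parts, by position, of the genes of each autosome (mean count at least 5, 0.5 added, sums of 50000 to 500000 UMIs), the position of each library between the tissue means (log2 CPM with 10 added, that library left out of the means), the comparison with 50 random draws of libraries left out, and 100 splits of the libraries not doubted.

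Alternatives tried were relative log expression scaling, DESeq2 1.42.0, no filter on genes, no title set, each set alone, a replicate block of the shared numbers, lenient (300 UMIs, 200 genes, 40% mitochondrial) and strict (1000 UMIs, 500 genes, 10%) cell filters, doublets kept, Leiden resolutions 0.5 and 2, other cell minimums and leaving out each library. Chosen after seeing the data were the fits without the doubted libraries (over 60% of barcodes past the mitochondrial limit, or under 100 kept cells), without normal replicate 1, and over genes higher in the class than in other cells.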

Results

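The data are UMI counts of single cells from mice of the KPC line, an engineered mouse model of pancreatic cancer, measured with droplet-based 5' RNA sequencing. There were 28 libraries, 16 from pancreatic tumors and 12 from uninvolved pancreas, here called normal. Their titles fall into 3 sets, named LDER, Un and, for titles with neither word, other here; the meaning of the set names is not given in the sources used here. Each set holds both tissues. The deposited matrices hold 72821 barcodes, 31053 genes and 337093303 UMIs, with 261999 to 64358519 UMIs per library. The median library held 8228149 UMIs among the tumors and 7801139 among the normals. After the filters 50344 barcodes were kept, 26593 from tumors (16 to 4885 per library) and 23751 from normals (35 to 8892 per library). 6 libraries were of doubtful quality: tumor replicates 9 and 10 and normal replicate 4, in which over 60% of barcodes had more than 20% mitochondrial UMIs, and tumor replicate 8 and normal replicates 9 and 11, with under 100 kept cells. Acinar enzyme genes, which are expressed by the digestive cells of the pancreas, took 28.3% of all UMIs in tumor replicate 6, 29.7% in normal replicate 9, 27.6% in normal replicate 11 and 5.87% in normal replicate 10. By Xist and genes of the Y chromosome, 9 libraries came from females, 5 of them tumors and 4 normals.

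The first comparison asked which cell types make up the kept cells of each tissue. Among these, tumors held more stromal and duct-type cells and more neutrophils, and the normals were dominated by lymphocytes. The shares are of barcodes that passed the filters and need not give the make-up of the tissue itself. Shares of kept cells were compared over 15 tumor and 10 normal libraries with at least 100 cells, by two-sided permutation tests within title set with Benjamini-Hochberg adjustment, and 10 of 16 classes passed. Fibroblast-like cells made up 6.34% ± 5.21 (SD, n = 15) of tumor cells and 0.790% ± 0.938 (SD, n = 10) of normal cells (adjusted p = 0.0103, permutation test), and 13 tumor libraries lay above the normal mean. Endothelial-like cells, which line vessels, rose from 0.266% ± 0.560 to 2.38% ± 2.12 (adjusted p = 0.00992). Pericyte or smooth muscle cells, which wrap vessels, made up 0.552% ± 0.870 of tumor cells and were not seen in the normals tested (adjusted p = 0.0339). Ductal-like cells, named by keratins and other epithelial genes, rose from 0.657% ± 0.900 to 24.5% ± 29.4 (adjusted p = 0.0225), with 14 tumor libraries above the normal mean. Neutrophils rose from 3.08% ± 3.59 to 15.5% ± 15.5 (adjusted p = 0.0225).

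T or NK cells fell from 38.9% ± 20.9 in the normals to 8.91% ± 13.6 in tumors (adjusted p = 0.00384), and 1 tumor library lay above the normal mean. B cells fell from 30.9% ± 12.9 to 6.48% ± 12.6 (adjusted p = 0.00640). Dendritic cells fell from 3.38% ± 1.28 to 1.51% ± 2.18 (adjusted p = 0.0339), mast cells or basophils from 0.329% ± 0.453 to 0.0197% ± 0.0447 (adjusted p = 0.0326), and endocrine cells from 0.537% ± 0.505 to 0.0530% ± 0.118 (adjusted p = 0.00992). Macrophages or monocytes made up 20.4% ± 16.9 of tumor cells and 17.6% ± 19.999 of normal cells (adjusted p = 0.782); without normal replicate 1, in which they were 69.3% of cells (95% Wilson interval 67.6 to 70.9), the normal mean was 11.9% (adjusted p = 0.184). Acinar, mesothelial, plasma and erythroid cells did not pass, with adjusted p of 0.840, 0.782, 0.233 and 0.276. Schwann cells were not found in either tissue. Cells given no class made up 9.60% ± 17.6 of tumor cells and 0.179% ± 0.280 of normal cells (adjusted p = 0.0929). Most of these are clusters that 1 tumor nearly fills, described with the chromosome profiles. Within a title set no class passed: 0 in LDER, 0 in Un and 0 in the other set, where the fewer libraries leave the permutation test little room.

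**Figure D1:**
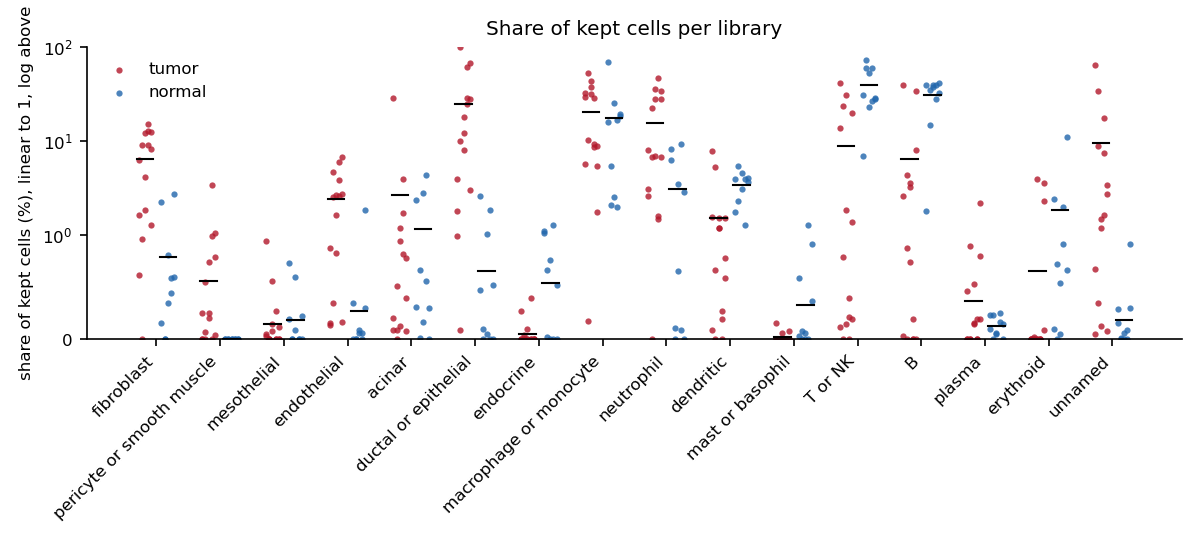
Share of kept cells (%, linear to 1 and logarithmic above) for each cell class, with 1 point per library of at least 100 kept cells (tumor red, normal blue) and a bar at each mean. Fibroblast-like cells average 6.34% in tumors and 0.790% in normals, and T or NK cells 8.91% and 38.9%.

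The second comparison asked how fibroblasts of the tumors differ from those of the uninvolved pancreas, the cell type the series title is about. Several contractile, matrix and TGF-beta response genes rose in tumor fibroblasts, and several genes of adventitial fibroblasts, the cells of vessel sheaths, fell. No list passed camera with an estimated correlation (lowest adjusted p = 0.127). UMI counts were summed per library over fibroblast-like cells for 14 tumors and 7 normals with at least 5 such cells, and tested with edgeR's quasi-likelihood test with title set in the model. Of 6534 genes tested, 238 rose and 162 fell in tumors (edgeR, adjusted p under 0.05), against 1322 at an unadjusted p under 0.05. The normals held few fibroblasts, 71 in normal replicate 1 and 6 to 15 in each of the others. The median log2 fold change of all genes was 0.16, so changes are relative to that shift. Leaving out the 4 doubted libraries of this class left 18 genes, and leaving out normal replicate 1 as well left 162; 397 and 400 of the 400 called genes kept their sign. Without normal replicate 8, 9 or 4 the count was 227, 234 or 266.

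Among the 10 genes with the smallest p that rose, several build or shape the matrix. Mgp (ENSMUSG00000030218, GRCm38 chromosome 6, 136872435 to 136875823), which encodes matrix Gla protein, an inhibitor of calcification, rose by a log2 fold change of 5.20 (SE 0.81, adjusted p = 0.000901, edgeR), from a mean of 134 to 4681 counts scaled to a library total (CPM), and all 14 tumors lay above the normal median. Tnc (ENSMUSG00000028364, chromosome 4, 63959785 to 64047015), the matrix protein tenascin C of wound tissue, rose by 6.38 (SE 1.12, adjusted p = 0.00190). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), the secreted phosphoprotein osteopontin, rose by 7.38 (SE 1.34, adjusted p = 0.00231); its level was lower in fibroblast-like cells than in the other cells of the same libraries, by a log2 ratio of -1.42, so RNA from other cells can add to it. Pappa, a protease that frees insulin-like growth factors, rose by 3.203. Mdk, the growth factor midkine, rose by 3.38, and Ncam1, an adhesion molecule also found on stellate cells, by 4.21. Cald1 and Palld, which bind and bundle actin, rose by 1.64 and 2.57. Btg2, an early response gene that slows growth, rose by 3.21.

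The 10 genes with the smallest p that fell were led by Antxr2 (ENSMUSG00000029338, chromosome 5, 97882783 to 98031043), a receptor for collagen VI, at -2.38 (SE 0.31, adjusted p = 0.000183, edgeR), with all 14 tumors below the normal median. Zfp385a, a regulator of p53 targets and of fat cell formation, changed by -2.76, and Dact2, an antagonist of Wnt and TGF-beta signalling, by -4.54. Nov (Ccn3), a secreted regulator of growth, changed by -2.83. Pcsk6, a protease that activates TGF-beta family precursors, changed by -4.02, and Car8, a relative of the carbonic anhydrases that binds an inositol receptor, by -4.94. C1qtnf2, a secreted relative of adiponectin, changed by -2.18, Entpd1 (CD39), which degrades extracellular ATP, by -3.82, Axl, the receptor kinase for Gas6, by -1.73, and Anxa3, a phospholipid-binding annexin, by -2.04. The genes named here were protein-coding, and all but 3 were higher in fibroblast-like cells than in other cells by a log2 ratio above 1; the exceptions were Spp1, Btg2 at 0.76 and Entpd1 at 0.70.

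**Figure D2:**
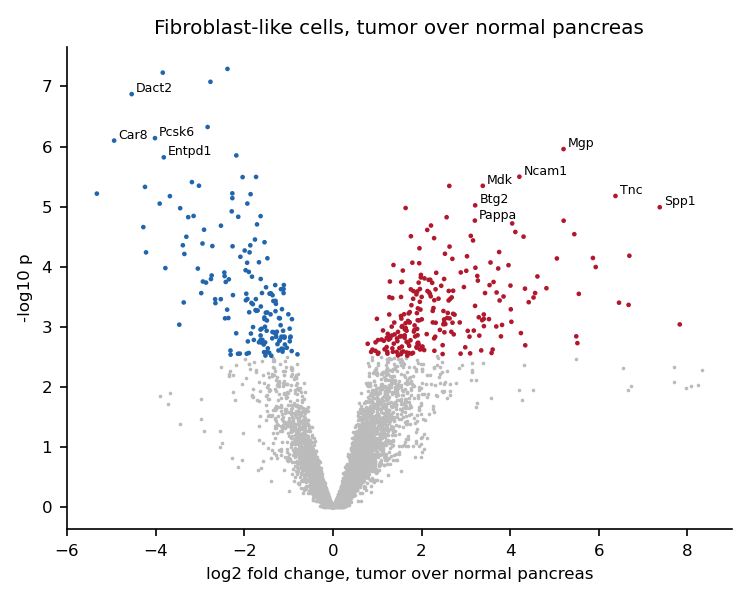
Log2 fold change of tumor over normal pancreas (x axis) against -log10 p (y axis) for the 6534 genes tested in fibroblast-like cells, with 238 that rose in red, 162 that fell in blue and the others grey. Named genes with a change of more than 3 in either direction are written beside their points, from Car8 at -4.94 to Spp1 at 7.38.

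Gene lists fixed before the data were examined group these changes. Of 14 myofibroblastic genes, 7 rose and none fell over all genes tested, and 10 rose when adjusted over the list alone; Tagln and Acta2, both of the contractile apparatus, rose by 5.21 and 4.30, Cxcl14, a chemokine, by 5.87, and Igfbp3, which binds insulin-like growth factors, by 3.73. The list passed camera with a preset correlation (adjusted p = 8.71e-06), not with an estimated correlation (adjusted p = 0.188 with an estimated correlation), and fry gave 0.0505. Of 15 adventitial genes, 9 fell and none rose, and 10 fell and 1 rose adjusted over the list alone (fry adjusted p = 0.00348; camera adjusted p = 1.02e-12 and adjusted p = 0.127 with an estimated correlation). Pi16, a marker of these cells, changed by -3.02, the guidance factor Sema3c by -3.31, the peptidase Dpp4 by -2.72 and the surface protein Cd34 by -2.53. Of 23 interstitial matrix genes, 5 rose and none fell (7 adjusted over the list alone; fry adjusted p = 0.0248; camera adjusted p = 0.167 with an estimated correlation). They were Timp1, an inhibitor of matrix proteases, at 3.96, the proteoglycan Bgn at 1.96, the collagen genes Col1a1 at 1.76 and Col1a2 at 1.13, and the protease Mmp14 at 1.34; Col3a1 at 0.59 did not pass.

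TGF-beta response genes moved with the contractile genes: of 12, 6 rose and 1 fell (9 and 1 adjusted over the list alone; fry adjusted p = 0.0400; camera adjusted p = 0.167 with an estimated correlation). Ltbp2, a matrix protein, rose by 4.01, the ligand Tgfb1 by 2.68 and the transcriptional regulator Skil by 2.33, and Ltbp1, which stores the latent ligand, changed by -1.60. Basement membrane genes went both ways, with Col15a1 up by 2.53 and Nid1 (-1.86), Lama2 (-1.73), Lamc1 (-1.30) and Lama4 (-1.11) down, of 11 (1 and 5 adjusted over the list alone; fry adjusted p = 0.0579). Of 16 inflammatory fibroblast genes, none rose and 3 fell over all genes, the actin-severing Gsn by a change of -3.14, Clec3b (tetranectin) -2.31 and the lipid phosphatase Plpp3 -1.62; 3 rose and 5 fell adjusted over the list alone, among them Il6, a cytokine, at 2.13 (fry adjusted p = 0.303). Of 11 antigen-presenting fibroblast genes, 2 rose, the protease inhibitor Slpi at 5.93 and the acute-phase gene Saa3 at 6.69, and Cd74 at 0.41 did not pass (2 adjusted over the list alone; fry adjusted p = 0.973).

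Of 17 glycolysis and hypoxia genes, 3 rose over all genes and 11 adjusted over the list alone (fry adjusted p = 0.0505; camera adjusted p = 0.198 with an estimated correlation), with the glycolytic enzymes Ldha at 1.47 and Pkm at 1.37 and the collagen-modifying P4ha1 at 0.89. Of 16 immediate early and heat shock genes, which respond to tissue dissociation too, 5 rose (12 adjusted over the list alone; fry adjusted p = 0.0111; camera adjusted p = 0.127 with an estimated correlation), including Jun at 1.82 and Fosb at 2.54. No member passed over all genes among 6 Hedgehog pathway genes (1 fell adjusted over the list alone), 11 interferon response genes or 9 proliferation genes (0 adjusted over the list alone in both), with fry adjusted p of 0.973, 0.370 and 0.655. Acinar enzyme genes, which fibroblasts do not express, had a median of -2.40 over 16 members (none past the threshold, fry adjusted p = 0.0111, down, camera adjusted p = 0.127 with an estimated correlation). This may reflect more free acinar RNA in the normal libraries, which was not measured.

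Fibroblast-like cells of the tumors were divided into sub-clusters to describe the populations, over 13 tumor libraries with at least 20 such cells and without a test. The population with the highest mean share, 31.4% ± 29.8 (SD), expressed Ly6c1, Clec3b, Dpt and the hyaluronan synthase Has1, and its mean for the inflammatory and adventitial lists lay 2.18 and 2.19 (log2) above the other populations; it held 97.8% of the fibroblast-like cells of tumor replicate 6 (95% Wilson interval 88.7 to 99.6). A population with Slpi, Saa3, Cd74 and Msln (antigen-presenting list 4.82 above the others) also had mesothelial genes, with Upk3b at 121, Upk1b at 143 and Nkain4 at 197 CPM beside Col1a1 at 6839 and the class II gene H2-Aa at 81.5. Its mesothelial marker score was 4.13, against 6.37 for the mesothelial sub-cluster. It averaged 20.5% ± 22.1 and reached 73.0% in tumor replicate 16 (61.0 to 82.4). A myofibroblastic population with Cxcl14, Actg2 and Thbs4 (list 2.77 above the others) averaged 16.5% ± 22.6, reached 68.9% in tumor replicate 7 (54.3 to 80.5), and had 192 tumor cells and 0 normal cells. A population with Ccl2, Tnfaip6 and Serpinb2 (inflammatory list 1.78 above the others) averaged 10.2% ± 10.5. Another, with the cartilage-type matrix genes Col11a1 and Comp and the Hedgehog target Ptch1, averaged 9.53% ± 20.004 and reached 57.4% in tumor replicate 5 (47.4 to 67.0). Cells with Hmga2, Col7a1 and Grem1 came almost all from tumor replicate 15, where they made up 88.3% of fibroblast-like cells (79.3 to 93.7). Proliferating cells averaged 3.38% ± 3.44. The Pi16, Sema3c and Efemp1 population of adventitial type (list 3.404 above the others) held 7 tumor cells and 54 normal cells, and averaged 0.949% ± 1.19 in tumors. Within-tumor shares differed widely between libraries, and both sides of the gene comparison are mixtures of these populations. Normal cells lay mostly in the Ly6c1 and Clec3b population, with 62 cells, and the Pi16 population, with 54. The gene comparison therefore cannot tell a change within fibroblasts from a change in the shares of populations.

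**Figure D3:**
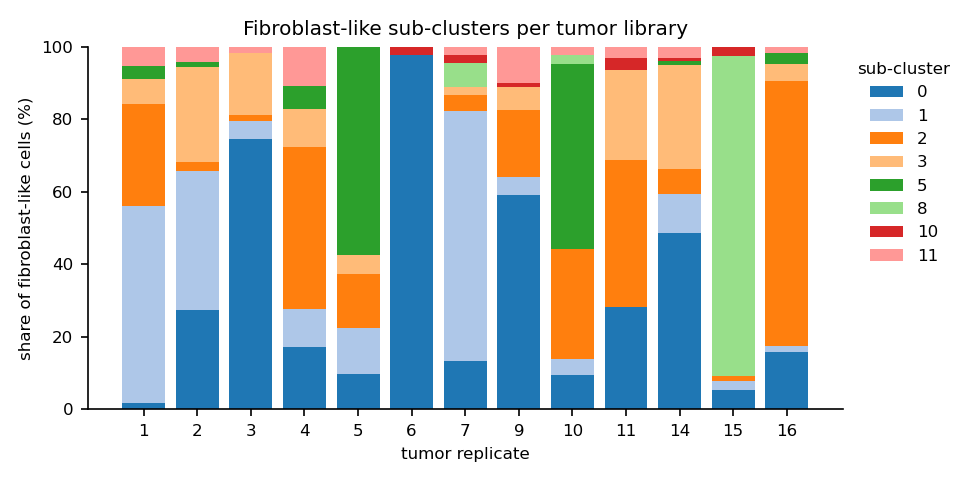
Share of fibroblast-like cells (%, y axis) in each sub-cluster (colours, numbered 0 to 11) for each tumor replicate (x axis) with at least 20 such cells. Sub-cluster 0, with Clec3b and Dpt, fills 97.8% of tumor replicate 6, and sub-cluster 8, with Hmga2, fills 88.3% of tumor replicate 15.

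Whether the tumor effect on fibroblasts differs between the LDER and Un sets was tested as an interaction. Over 5 LDER tumors, 3 LDER normals, 3 Un tumors and 3 Un normals, 0 of 5521 genes passed (edgeR), with 412 at an unadjusted p under 0.05 and 0 with relative log expression scaling. Without the filter on genes 106 of 17157 passed, and with the replicate block, over 2 libraries per tissue and set, 15 of 4036. Tested within a set, 249 genes passed in LDER alone and 170 in Un alone (edgeR).

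The third comparison was of ductal-like cells, between 15 tumors and 4 normals with at least 10 such cells. The normals were replicates 3, 4 and 6 of the Un set and replicate 1 of the other set. With title set in the model and no LDER normal, the LDER tumors informed the spread and not the tissue difference. In the other set the tumors were set against normal replicate 1 alone, which lies with the tumors in gene expression, as described below. Genes past the threshold were almost absent, and none of 10 duct function genes passed. Of 10347 genes 1 passed (edgeR), against 1910 at an unadjusted p under 0.05 and 548 with DESeq2. It was Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381), the insulin gene of beta cells, at -5.71 (SE 0.89, adjusted p = 0.0220, edgeR). Ductal-like cells had less of it than other cells by a log2 ratio of -8.14, so it may come from free RNA of islets, which was not measured. The model recovered 40.8% of 4-fold and 68.4% of 8-fold changes placed in simulated counts of this size. Without normal replicate 1 the count was 649, and without tumor replicate 6 it was 106. Leaving out any other library gave 0 to 4 genes: 0 without tumor replicate 4 or 13, 2 without tumor replicate 2, 8, 9 or 10 or normal replicate 4, and 4 without normal replicate 3 or 6. Within the Un set 762 of 2340 genes passed (3 tumors and 3 normals).

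The clusters behind this class differ between tissues: clusters 3 and 27 held 75.1% and 14.8% of the tumor ductal-like cells, and cluster 29 held 60.5% of the normal ones. Of cluster 27, 84.5% came from tumor replicate 3. Of 10 duct function genes none passed over all genes, and 2 rose and 4 fell adjusted over the list alone (median -1.88; fry adjusted p = 0.0245, down; camera adjusted p = 0.150 with an estimated correlation). Among those that fell were the duct transcription factor Onecut1 at -3.90, Bicc1, an RNA-binding protein of tubules, at -1.99, and the cilium gene Dcdc2a at -4.48; the bicarbonate carrier Slc4a4 at 1.55 and the water channel Aqp1 at 2.55 rose. Glycolysis and hypoxia genes had 12 of 18 past the threshold adjusted over the list alone, all higher, and 0 over all genes (fry adjusted p = 0.0503), with Ndrg1 at 3.01, Pkm at 2.43 and Vegfa at 1.86. Classical pancreatic tumor genes had 2 of 15 on that scale, the surface protein Msln at 2.86 and the transcription factor Onecut2 at 2.42 (0 over all genes; fry adjusted p = 0.356). Of 9 mesenchymal genes 1 was higher and 1 lower adjusted over the list alone, the latter the matrix gene Sparc at -3.77 (0 over all genes; fry adjusted p = 0.915). Immediate early genes had 5 of 16 higher adjusted over the list alone (fry adjusted p = 0.0715), and interferon and proliferation genes had 0 (fry adjusted p = 0.295 and 0.581). Acinar enzyme genes lay lower in tumors (median -3.83 over 18; fry adjusted p = 0.00148; camera adjusted p = 0.0457 with an estimated correlation).

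In macrophages and monocytes of the tumors glycolytic, hypoxic, lipid-handling and inflammatory genes were among those that rose, and several interferon response genes fell. No list passed camera with an estimated correlation (lowest adjusted p = 0.0826). Over 13 tumors and 9 normals with at least 20 cells, 909 of 8794 genes rose and 535 fell (edgeR, adjusted p under 0.05; 2477 at an unadjusted p under 0.05). Within sets 283 passed in LDER and 1742 in Un. Without the doubted libraries 819 passed, and all 1444 kept their sign. The tissues drew on different clusters: 7, 14, 18 and 19 held 28.0%, 16.5%, 14.4% and 13.3% of the tumor cells, and 6 and 17 held 46.2% and 25.2% of the normal cells. Most of these rest on single libraries. Clusters 7, 14, 18 and 19 drew 91.1%, 71.2%, 60.8% and 85.7% of their cells from 1 tumor each. Cluster 6 drew 77.2% from normal replicate 1, and cluster 17 drew 24.2% from normal replicate 6. Normal replicate 1 lies with the tumors in gene expression, as described below, so cluster 6 need not stand for normal pancreas.

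Basp1 (ENSMUSG00000045763, chromosome 15, 25363277 to 25413764), a membrane protein that binds actin regulators, led the genes that rose at 3.27 (SE 0.34, adjusted p = 6.95e-06, edgeR), with 13 of 13 tumors above the normal median. Slc2a1, the glucose transporter GLUT1, rose by 3.17, Tnfrsf12a, the TWEAK receptor, by 2.40, the glycosyltransferase gene Mgat4a by 2.29 and the transcription factor Sox4 by 3.71. Calhm2 (ENSMUSG00000033033, chromosome 19, 47105353 to 47138294), an ATP-releasing channel, changed by -2.79 (SE 0.33, adjusted p = 1.28e-05), Cd209b, a lectin of tissue-resident cells, by -4.46, Nfam1, an activating receptor, by -1.19, Tgfbr3, a TGF-beta co-receptor, by -3.28, and S1pr5, a lipid receptor of patrolling monocytes, by -5.85. Of 16 glycolysis and hypoxia genes 15 rose (16 adjusted over the list alone; fry adjusted p = 2.56e-05; camera adjusted p = 3.12e-12 and adjusted p = 0.0826 with an estimated correlation), with the angiogenic factor Vegfa at 5.47, the oxygen sensor Egln3 at 4.49 and Bnip3, of mitophagy, at 2.60. Of 13 inflammatory monocyte genes 10 rose and 1 fell (10 and 2 adjusted over the list alone; fry adjusted p = 0.000992; camera adjusted p = 0.211 with an estimated correlation): the chemokine Cxcl3 at 6.47, the cytokine Il1b at 4.95 and the prostaglandin synthase Ptgs2 at 4.91 were higher, and the monocyte surface gene Ly6c2 lower at -2.68. Of 16 lipid-associated and hypoxic macrophage genes 10 rose and 1 fell (12 and 2 adjusted over the list alone; fry adjusted p = 0.00173; camera adjusted p = 0.211 with an estimated correlation), with the arginine-degrading Arg1 at 5.83, Spp1 at 5.41, Gpnmb, a lysosomal glycoprotein, at 4.11, the lipid receptor Trem2 at 1.33 and the fatty acid transporter Cd36 at -1.75.

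Interferon response genes went the other way: 5 of 14 fell, including the transcription factor Irf7 at -1.65, and none rose (9 fell adjusted over the list alone; fry adjusted p = 0.0110; camera adjusted p = 0.246 with an estimated correlation). Of 12 resident macrophage genes the mannose receptor Mrc1 rose by 1.56, and Lyve1 (-1.94) and the receptor Timd4 (-4.16), which takes up dying cells, fell (1 and 5 adjusted over the list alone; fry adjusted p = 0.170). None of 7 MHC class II genes passed (0 adjusted over the list alone; fry adjusted p = 0.301). Of 16 immediate early genes 5 rose (6 adjusted over the list alone; fry adjusted p = 0.0152; camera adjusted p = 0.246 with an estimated correlation), with Fosb at 1.67. Of 14 proliferation genes Mki67 rose by 1.04 over all genes, and 0 did adjusted over the list alone (fry adjusted p = 0.279). Genes of other cell types moved as well: Col1a1, a fibroblast gene, at 3.41 and the keratin Krt18 at 2.08 were higher in the tumor class, all 4 haemoglobin genes were lower, and 2 of 17 acinar enzyme genes were lower (10 adjusted over the list alone; fry adjusted p = 0.000298; camera adjusted p = 0.158 with an estimated correlation).

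T or NK cells, called T cells here and below, were compared between 7 tumors and 10 normals with at least 20 cells. Cluster 20, with the NK cell genes Gzma, Ncr1 and Klrk1, held 5.57% of the tumor cells and 8.53% of the normal cells of this class. Several early response genes and the checkpoint receptor gene Ctla4 rose, and no list passed camera with an estimated correlation (lowest adjusted p = 0.346). Of 9427 genes 504 rose and 380 fell (edgeR, adjusted p under 0.05; 2416 at an unadjusted p under 0.05). LDER alone gave 2105. The count was 1531 without tumor replicate 2, 1428 without normal replicate 1, 582 without tumor replicate 11, 494 without tumor replicate 14, 413 without tumor replicate 12, 378 without normal replicate 10 and 320 without normal replicate 8. Cluster 5 held 44.9% of the tumor cells and 10.0% of the normal cells, and cluster 0, 90.6% of it from 1 library, 9.51% and 43.4%.

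Neurl3 (ENSMUSG00000047180, chromosome 1, 36264597 to 36274679), a ubiquitin ligase gene, led at 1.72 (SE 0.16, adjusted p = 1.19e-05, edgeR), with 7 of 7 tumors above the normal median. The clock gene Per1 rose by 2.79, Skil, a brake on TGF-beta signalling, by 1.59, Zc3h12a (regnase-1), an RNase that limits cytokine mRNA, by 1.82 and Prr7, an adaptor of T cell signalling, by 1.45. Golga1 (ENSMUSG00000026754, chromosome 2, 39016155 to 39065541), of the Golgi, changed by -1.91 (SE 0.26, adjusted p = 0.000414), the tetraspanin Tspan32 by -1.52, the membrane protein gene Tmem19 by -1.22, the mitochondrial deacylase Sirt5 by -1.51 and Ccdc71 by -1.43. Of 7 exhaustion genes Ctla4 rose by 1.69 (1 adjusted over the list alone; fry adjusted p = 0.142). No gene passed among 8 cytotoxic, 8 naive and 8 regulatory genes (0 adjusted over the list alone in each; fry adjusted p = 0.303, 0.559 and 0.806). Of 16 immediate early genes 5 rose (10 adjusted over the list alone; fry adjusted p = 0.0118; camera adjusted p = 0.346 with an estimated correlation), with Atf3 at 3.70 and Nr4a1, which also marks receptor signalling, at 2.81. Of 16 glycolysis and hypoxia genes Vegfa rose by 4.57 and Slc2a1 by 0.70 (3 adjusted over the list alone; fry adjusted p = 0.0118; camera adjusted p = 0.371 with an estimated correlation), and of 13 proliferation genes Mcm5, of DNA replication, by 0.64 (1 adjusted over the list alone; fry adjusted p = 0.0705). None of 14 interferon genes passed (0 adjusted over the list alone; fry adjusted p = 0.702). All 4 fibroblast markers measured were higher in tumor T cells, Col3a1 by 5.53 and Dcn by 4.13, as were the keratins Krt8 by 3.70 and Krt18 by 3.49. These genes of other cells may reflect free RNA in the tumor libraries, which was not measured. Acinar enzyme genes lay lower (fry adjusted p = 0.0133; camera adjusted p = 0.346 with an estimated correlation; 0 of 19 over all genes), as did 3 of 4 haemoglobin genes.

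The endothelial comparison could not be made, since no normal library held 20 endothelial-like cells; normal replicate 1 held 11. The series title names copy number inferred from RNA, so expression was summarised along the chromosomes of each tumor. The ductal-like cells had the more uneven profiles at the usual minimum count, not at a higher one, and no match of fibroblast-like with ductal-like profiles of the same tumor was detected. The SD over the 19 autosomes of the median log2 ratio to other tumors' cells of the class was 0.195 for ductal-like, 0.144 for fibroblast-like and 0.136 for macrophage-like cells (11 libraries; exact two-sided sign-flip test, p = 0.0137 for ductal-like against fibroblast-like and 0.0166 against macrophage-like). Over genes with at least 20 counts the differences were 0.0133 and 0.0333 (exact test, p = 0.771 and 0.398), against 0.0513 and 0.0595 at the usual minimum. Pearson's r between the fibroblast-like and ductal-like profiles of the same tumor averaged 0.0282, against 0.00585 between different tumors (12 tumors, one-sided permutation p = 0.388). For fibroblast-like and macrophage-like cells of the same tumor it averaged 0.311 (permutation p = 0.000390), and for macrophage-like and ductal-like cells 0.0824 (permutation p = 0.130). Partners were permuted over all title sets, so a batch shared by both classes was not taken out.

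A change of copy number moves the genes along a chromosome together. The genes of each autosome were therefore divided by position into 2 equal parts, and the log2 ratio of a class to the fibroblast-like cells of the same tumor was correlated between the parts over the autosomes. For ductal-like cells r averaged 0.593 ± 0.311 (SD, 12 tumors), from -0.0583 in tumor replicate 1 to 0.927 in tumor replicate 15, and 8 of 12 passed after adjustment (permutation test). In tumor replicate 15, where 88.3% of the fibroblast-like reference are cells of an Hmga2 population, macrophage-like cells reached 0.816 and passed too, and ductal-like against macrophage-like cells gave -0.0712, so that value need not come from the ductal-like cells. Means were 0.113 for macrophage-like, -0.210 for endothelial-like, -0.100 for neutrophil-like and 0.181 for T cell-like cells. The ductal-like value was above the macrophage-like one in 9 of 11 tumors (mean difference 0.486, exact two-sided sign-flip test, p = 0.00684), above the endothelial-like one in 6 of 6 (p = 0.0313 by the exact test, the smallest it can give) and above the neutrophil-like one in 9 of 9 (p = 0.00391 by the exact test, the smallest it can give). Set against macrophage-like cells instead, ductal-like cells exceeded fibroblast-like cells by 0.347 (11 tumors, exact test, p = 0.0371). With every sum thinned to the smallest, the differences to macrophage-like and to fibroblast-like cells no longer passed (exact test, p = 0.319 and 0.205), while those to endothelial-like (0.464, 6 of 6 tumors, p = 0.0313, the smallest it can give) and neutrophil-like cells (0.462, 8 of 9, p = 0.00781) did. Ductal-like cells then averaged 0.339 against fibroblast-like cells with 2 of 12 passing, and macrophage-like cells 0.254, also with 2 of 12. Without thinning but with the mean over genes, 4 of 12 passed for ductal-like cells.

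Clusters without a class that come almost wholly from 1 tumor had high values on this measure. Tumor replicate 1 had 2267 cells in clusters with Krt18, Tm4sf1, Hmga2 and Cdkn2a, which had too few or too weak markers for any class, with r of 0.904 against fibroblast-like cells. Tumor replicate 7 had 1529 cells in clusters with Spp1, Sfrp2, Sparc and Cdkn2a, scored highest for fibroblasts but left out for coming from 1 library or for few UMIs, with r of 0.876. The 68 cells of tumor replicate 15 in the Hmga2 population of the fibroblast-like class had r of 0.721 against macrophage-like cells, and the other 9 fibroblast-like cells of that tumor -0.227. With every sum thinned to the smallest, against the same references, r was 0.430, 0.788 and 0.506 for tumor replicates 1, 7 and 15. Only that of tumor replicate 7 then passed. Mean Hmga2, a chromatin protein of embryonic and tumor cells, was 430, 255 and 408 CPM in these groups, and Cdkn2a, a tumor suppressor locus, 987, 2143 and 502.

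**Figure D4:**
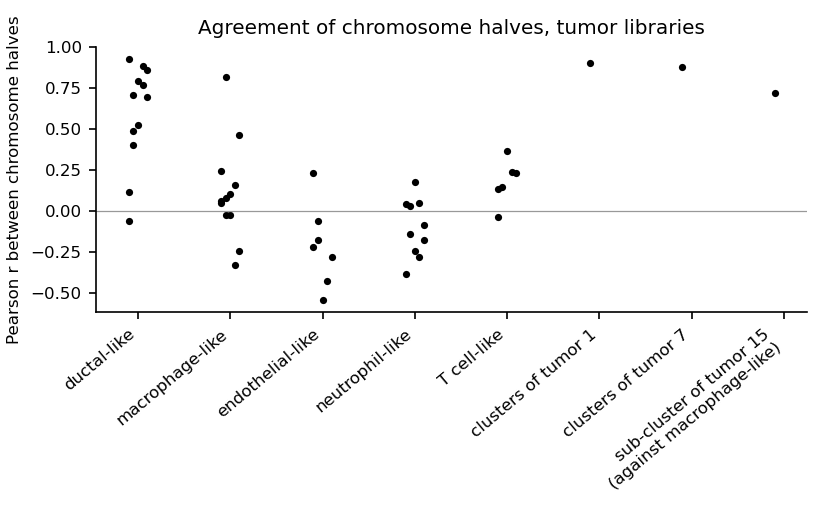
Pearson's r between the 2 parts of the autosomes (y axis) of the log2 ratio of each class to the fibroblast-like cells of the same tumor, with 1 point per tumor library; the last column is against macrophage-like cells. Ductal-like cells average 0.593, and the clusters of tumor replicates 1 and 7 lie at 0.904 and 0.876.

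Each library was also placed between the tissues, class by class, on a scale where the mean of the other normals is 0 and that of the other tumors is 1. Normal replicate 1 lay at 0.819 to 1.19 in the 7 classes measured, with a mean of 0.962, and was the farthest of its tissue in 7 of 7. The other normals lay between -0.271 and 0.571, the highest of them normal replicate 2, and tumor values went down to 0.414 in tumor replicate 11 and 0.478 in tumor replicate 6, so the tissues overlap. Counts of called genes without normal replicate 1 were 566 in fibroblast-like, 649 in ductal-like and 1428 in T cells.

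**Figure D5:**
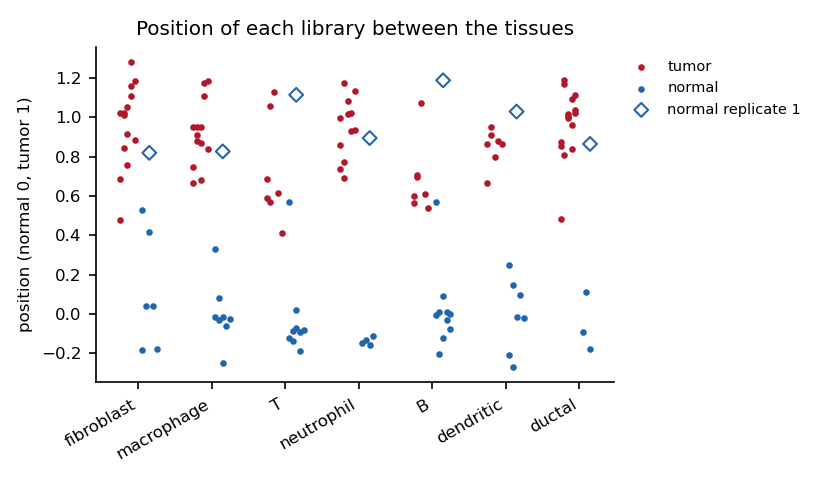
Position of each library (1 point per library and class) between the mean of the other normal libraries (0) and that of the other tumor libraries (1), with tumors red, normals blue and normal replicate 1 as open diamonds. Normal replicate 1 lies at 0.819 to 1.19, among or above the tumor libraries, in the 7 classes measured.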

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

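All tests in this part were chosen only after the results were seen. In 7 of 30 groups of libraries examined, the most extreme library lay apart from the others by Dixon's criterion. Chance would give about 1.5 if the groups were independent and normally distributed. Shares are bounded at 0 and the same libraries recur across groups, so the 2 numbers do not measure an excess over chance. Normal replicate 12 was apart in 3 shares: endothelial-like cells at 1.82% (2 of 110 cells, 95% Wilson interval 0.50 to 6.39%), erythroid cells at 10.9% (6.35 to 18.1%) and cells without a class at 0.909% (0.161 to 4.97%). The larger erythroid cluster also had B cell genes among its leading genes, with a score of 9.87 for erythroid and 4.92 for B cells. Haemoglobin genes took 17.5% of all UMIs of normal replicate 12, so its erythroid share need not be erythroid cells alone. Tumor replicate 5 was apart among the tumors in the position of its B cells between the tissues, at 1.07. Normal replicate 1 was apart in 3 measures: macrophages or monocytes at 69.3% of its cells (67.6 to 70.9%), and the positions of its neutrophils at 0.894 and of its dendritic cells at 1.03, where the normals average near 0 and tumors near 1.

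Normal replicate 1 lies with the tumor libraries in gene expression as well as in part of its cell shares. A shift of its title set alike in both tissues is argued against: tumor libraries of the same set lay above the other tumors by at most 0.360 of this library's distance from the other normals, over 7 classes. A shift of the normals of the set alone cannot be told apart from a difference of this 1 library: normal replicate 2, the only other normal of that set, lay 0.273 to 0.550 as far from the normals of the other sets as this library in the 4 classes measured, which 1 library does not settle. A wrong label, with tumor tissue in this tube, may explain it, since in 7 of 7 classes the library lay at or above the lowest tumor library. Other values go with its label: endocrine cells were 1.04% of its cells (95% Wilson interval 0.745 to 1.46%), where tumors average 0.0530% ± 0.118 and normals 0.537%, and endothelial-like cells 0.348% (0.194 to 0.622%), where tumors average 2.38%, so a wrong label stays open. Whether its ductal-like cells carry chromosome changes like those of the tumors cannot be told apart from noise: the 2 parts of the autosomes agreed past an adjusted p of 0.05 in 1 of 8 settings and reference classes, with r of 0.627 over genes with at least 20 counts against fibroblast-like cells and -0.0590 at the usual minimum. In that 1 setting its T cells (0.550) and macrophages (0.473) passed too, so the value is not particular to ductal-like cells and may come from the shared reference. Uninvolved pancreas beside a tumor that has come to resemble it, which the labels' tissue allows, remains open and was not tested.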

How the results depend on the processing

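Tests of libraries left out for quality, of random draws and splits beside them, of single sets in the cell shares, of paired libraries without the block, of genes higher than in other cells, of thinned chromosome parts and of every exploratory class were chosen only after the results were seen. Single genes named for their smallest p, not the list members, kept their direction in all 760 alternatives: 728 stayed past the threshold, 32 no longer passed it and 0 reversed. Of 253 alternatives for the share of a single class, 197 kept direction and side of the threshold, 46 were weaker, 1 was stronger and 9 reversed. The 9 reversals were in classes that had not passed. The difference for acinar cells became -1.02 percentage points with the lenient filter, -0.648 with the strict filter, -0.898 at resolution 2 and -1.02 in the LDER set alone. For mesothelial cells it became 0.0203 in LDER alone and 0.0310 with the replicate block, and on leaving out 1 library it ranged from -0.0563 to 0.0246, the latter without normal replicate 1. It became -14.1 for macrophages in the other set alone, and for plasma cells -0.101 in Un alone. With the lenient and strict filters the acinar class took in a cluster with T cell genes, of 341 and 395 cells. Normal replicate 8 gave 44.6% and 38.0% of these cells. The main setting had no such cluster in the class, so these acinar reversals need not be a change in acinar cells. With doublets kept the class held one too, of 420 cells, without a reversal. The number of classes past the threshold, 10, became 0 in each of the 3 sets alone and 4 with the replicate block; fewer libraries limit the permutations there.

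In fibroblast-like cells the 400 genes became 617 with DESeq2, 680 without the filter, 249 in LDER alone, 170 in Un alone, 131 with the replicate block and 114 in the same paired libraries without it, and 227 to 566 on leaving out 1 library. The median log2 change of all genes was 0.16, 0.41 without the filter and 0.39 in LDER alone. Without the doubted libraries 18 genes passed. Of 50 random draws that left out as many libraries per tissue, 5 gave as few or fewer, with a median over the draws of 141 and a range of 6 to 555. Each of those 5 also left out 1 doubted library, and draws without any gave 53 to 433 genes. Fewer libraries may account for the drop, but the draws cannot tell this apart from the loss of single doubted libraries. A difference carried by the doubted libraries alone is argued against: of 100 splits of the other libraries within title set, 1, the real one, called as many as 18 genes, and the highest other called 12. For 397 of the 400 genes the median change in the called direction was 1.95 (quartiles 1.54 and 2.83, median SE 0.48) with and 1.78 (1.34 and 2.67, 0.56) without the doubted libraries; the calls ended with a somewhat smaller change and a larger SE. Without these and normal replicate 1, 162 passed.

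In ductal-like cells the count of 1 became 548 with DESeq2, 4 without the filter, 418 without title set, 762 in Un alone, 750 with the replicate block, 408 in those paired libraries without it, 0 among genes higher than in other cells, and 0 to 649 on leaving out 1 library. In macrophages 1444 became 283 in LDER alone and 819 without the doubted libraries. In T cells 884 became 1538 without the filter, 271 without title set, 2105 in LDER alone, 1659 in paired libraries without the block, 1351 without the doubted libraries and normal replicate 1, and 320 to 1531 on leaving out 1 library. In neutrophils 835 became 228 without the doubted libraries, 338 without normal replicate 1 as well, and 1304 without that library alone. In B cells 1057 became 681 among genes higher than in other cells. In dendritic cells 238 became 367 with DESeq2, 575 without normal replicate 1 and 567 without the doubted libraries too. The interaction of tissue with set, 0, became 106 without the filter, 15 with the replicate block and 0 to 3 on leaving out 1 library, 3 without tumor replicate 7. The block also left only 2 libraries per tissue and set, so its own part in the 15 cannot be told. Beyond the number of libraries or genes tested the cause was not tested.

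Over the 4 planned classes tested, fry called 27 lists, camera with the preset correlation 37 and camera with an estimated correlation 3, all of these 3 in ductal-like cells. The excess spread over chromosomes of ductal-like cells no longer passed over genes with at least 20 counts, at 0.0133 above fibroblast-like and 0.0333 above macrophage-like cells. With every UMI sum thinned to the smallest, the excess agreement of chromosome parts was 0.0874 over macrophage-like and 0.196 over fibroblast-like cells, neither past the threshold. It was 0.464 over endothelial-like and 0.462 over neutrophil-like cells, both past it. The match of fibroblast-like and ductal-like profiles stayed short of the threshold in each setting, with one-sided permutation p of 0.325 to 0.668, and 0.197 to 0.707 on leaving out 1 tumor.

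Planned fits that were not run, for too few libraries, were those of endothelial-like cells, of fibroblast-like cells at a minimum of 10, 20 or 50 cells, of ductal-like cells at 20 or 50 cells and in LDER alone, of the other set alone in each class, of T cells in Un alone, of the interaction at a minimum of 10 or 20 cells, and the chromosome profile against normals. In simulated counts 2-fold changes were recovered least in ductal-like cells (0%), neutrophils (10.8%) and fibroblast-like cells (15.5%), so changes of that size can be missed there.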

Other observations

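All tests in this part were chosen only after the results were seen. Neutrophils, B cells and dendritic cells were compared between the tissues as well (edgeR). In neutrophils of 12 tumors and 5 normals 429 of 4014 genes rose and 406 fell. The normals were replicates 3, 4, 5 and 6 of the Un set and replicate 1 of the other set. With no LDER normal and title set in the model, the LDER tumors did not inform the tissue difference. In the other set the tumors were set against normal replicate 1 alone, whose label is in doubt. Cd274, which encodes the checkpoint ligand PD-L1, rose by 3.61, the activin gene Inhba by 6.66, the focal adhesion gene Tes by 2.63, Egln3 by 3.49 and the adaptor gene Pik3ap1 by 3.78, and the calcium channel Trpm2 (-3.47), Padi4 (-3.61), which citrullinates histones in neutrophil traps, Rnase6 (-5.17) and Anxa1 (-2.63), a brake on inflammation, fell. Ins2 changed by -5.53, which may reflect free islet RNA. Of 16 glycolysis and hypoxia genes 10 rose (12 adjusted over the list alone; fry adjusted p = 0.0222; camera adjusted p = 0.268 with an estimated correlation), among them Ero1l at 4.04, Hk2 at 2.82 and Vegfa at 3.18. The heat shock genes Hspa1a and Hspa1b rose by 4.46 and 2.999, and Fos changed by -1.55. Cluster 10 held 43.2% of the tumor and 0.556% of the normal neutrophils, and cluster 28 0.289% and 63.0%. Without normal replicate 1 the count was 1304, and without the doubted libraries 228.

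In dendritic cells of 7 tumors and 8 normals 167 of 5409 genes rose and 71 fell. Without normal replicate 1 the count was 575. Ifitm1, an antiviral membrane protein, rose by 5.04, the decoy receptor Il1r2 by 4.67, the endocytic adaptor Dab2 by 2.91, Vegfa by 4.13 and S100a6 by 1.26, and Hmgn3 (-1.64), Triobp (-1.68), Tmem158 (-3.82), Rnase6 (-1.71) and Calhm2 (-2.37) fell. Of 14 glycolysis and hypoxia genes 7 rose (12 adjusted over the list alone; fry adjusted p = 0.00390; camera adjusted p = 0.104 with an estimated correlation), with Slc2a1 at 2.09 and Ldha at 1.02. In B cells of 7 tumors and 11 normals 631 of 8521 genes rose and 426 fell. Of 16 immediate early genes 10 rose (12 adjusted over the list alone; fry adjusted p = 0.00655; camera adjusted p = 0.212 with an estimated correlation), with Nr4a1 at 4.15 and Egr1 at 2.58, and Hs3st1, Ifrd1 and Gpr171 rose by 2.90, 2.26 and 2.55, while Slfn2, which keeps lymphocytes quiescent, changed by -1.66. Genes of other cells changed as well: all 19 acinar enzyme genes fell (19 adjusted over the list alone), with Cpb1 at -7.55, as did the pancreatic genes Rnase1 (-6.62), Pla2g1b (-4.96), Gp2 (-6.11) and Klk1 (-6.40), and the 3 fibroblast markers measured rose, with Col3a1 at 6.17, as did Spp1 by 8.58 and Sparc by 6.09.

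Libraries were also split in other ways of the same sizes within title set, 100 splits each with the real one. In fibroblast-like cells only the real split called as many as 400 genes, with at most 43 in another split, which argues against chance. The same held for macrophages, with 1444 against 521, for T cells, with 884 against 198, and for B cells, with 1057 against 361. In neutrophils, with 835 against 914, and dendritic cells, with 238 against 240, 2 splits were as large, the real one included. Another labelling called more genes there than the real one, so chance is not excluded. For ductal-like cells chance cannot be excluded either, where 8 splits called at least the real count of 1 and the highest called 877. For the interaction the real count is 0, so all 100 splits call at least as many whatever the data, which says nothing about chance; the highest called 72. The splits that called 877, 914 and 240 genes each exchange normal replicate 1 with a tumor library, tumor replicate 6, 6 and 2, and leave the other labels as they are. Exchanged with tumor replicate 1, 3, 4 or 5 instead, it gave 0 genes in ductal-like cells, and with tumor replicates 1 to 5 it gave 63 to 412 in neutrophils, so the high counts may rest as much on tumor replicate 6.

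A group of cells from each of 3 tumors (replicates 1, 7 and 15) expressed Hmga2 and almost no Epcam. Those of tumor replicates 7 and 15 had fibroblast genes. Those of tumor replicate 1 scored highest for ductal cells, at 1.78 and 1.73, too low for a class, with Krt18 at 589 CPM and Vim, an intermediate filament gene of mesenchymal and other cells, at 2435, against 541 in its ductal-like cells. A hypothesis is that these are carcinoma cells that have moved, to different extents, towards a mesenchymal state. For mesenchymal carcinoma cells speaks that all 3 groups had agreement of the 2 chromosome parts above that of endothelial-like, neutrophil-like and T cell-like cells. Against macrophage-like cells the groups had 0.849, 0.827 and 0.721, and the highest value of those classes was 0.530. Fibroblast-like cells, which in tumor replicate 15 are mostly the Hmga2 cells, reached 0.757 and passed in 2 of 12 tumors. That highest value lies above the group of tumor replicate 15. RNA from ductal-like cells of the same library is argued against: Epcam reached at most 0.714% of the ductal-like level, with Cdkn2a at 360%, 1514% and 522% of it. The expression of the cell type at the greater depth of these groups may still account for the agreement, so it cannot be told apart from a copy number change. With every UMI sum thinned to the smallest, the groups had 0.556, 0.642 and 0.506. Only 1 of the 3 stayed above endothelial-like, neutrophil-like and T cell-like cells, whose highest value was 0.604. For tumor replicates 1 and 7 these cells were outside the fibroblast-like class, and adding those of tumor replicate 7 to it gave 332 called genes.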
